A study of Homo sapiens with 9 samples.

How the data were processed

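RNA sequencing libraries were made from Cal-27 cells, a line of tongue squamous carcinoma cells grown in high-glucose medium with fetal bovine serum. Per the labels' protocols, the cells were co-cultured for 48 h with exosomes of cancer-associated fibroblasts or with hOMF exosomes (an abbreviation the labels do not spell out and write in 2 ways), or served as control, with 3 replicate samples in each of 3 groups. Total RNA with an RNA integrity number above 7.0 was used, 5 µg per library. Poly(A) RNA was selected, the second strand was marked with dUTP and removed, and paired reads of 150 nucleotides were sequenced on an Illumina NovaSeq, per the labels' protocols.

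The authors deposited 1 table of 16366 genes with human gene symbols and NCBI gene identifiers. Per the file headers it holds, for each library, the authors' expected counts, FPKM and TPM, together with the authors' means of each group, which were not used. Per the submitters' processing notes RSEM 1.2.8 and Bowtie2 2.2.5 were used, so the expected counts are RSEM estimates that share reads between similar genes. The processing notes name a mouse genome build, although all identifiers and symbols in the table are human, so the build behind the counts is uncertain, and no coordinates in the text come from the authors' table. The annotation and the strand setting of the counting are not given in the sources used here. FPKM values deposited by the authors are fragments scaled by transcript length and sequencing depth, and TPM values deposited by the authors are scaled to the same sum in each library. The TPM values were not tested. Each column of values was assigned to a sample by its name, which the labels list, and 0 columns were left without a sample.

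Expected counts summed to 11192908 to 12779101 per library, and between 90.5% and 92.0% of the values in a library, including those at 0, were whole to within 0.001. They were rounded to whole numbers before testing. The table holds 0 of the genes encoded in the mitochondrial genome. MTRNR2L2 and MTRNR2L8, nuclear genes that resemble mitochondrial ribosomal RNA, together took 3.52% to 4.76% of the counts of a library, and the 50 most abundant genes took 17.4% to 18.8%. Replicate libraries of a group differed by more than sampling noise, with chi-square per degree of freedom between 3.14 and 11.4, which separate preparations of one culture could also give. Each library was counted as a sample because the labels call it a replicate sample. Spearman correlations of log2 CPM within groups were 0.992 to 0.996.

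The test written before the data were examined was limma on log2(FPKM + 1), to be replaced by edgeR if counts were in the table, which they were. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), leaving 12470, and libraries were scaled by TMM. The quasi-likelihood fit (glmQLFit, glmQLFTest, two-sided) held all 9 libraries and the group as the only term, with 6 residual degrees of freedom, and the 3 comparisons were taken from this fit with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. SE values were computed from the fold change and the square root of the F statistic, and intervals cover 95%. CPM values are TMM scaled. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, python 3.11.15 and matplotlib 3.10.9.

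Groups, designs, most alternatives, the rule for named genes and 44 gene lists were fixed before the data were examined. The lists cover immune, squamous, stromal, cell cycle, stress and metabolic genes and markers of fibroblasts, endothelium and leukocytes. The lists with at least 5 tested members, 42 of them, were tested with camera of limma at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, with adjustment over the 126 tests of lists. The endothelial list (4 tested members) and the list of mitochondrially encoded genes (0 in the table) were not tested. No list call held at an adjusted p under 0.05 with an estimated correlation. The rule for named genes took, in each comparison, the 10 called genes with the largest rise and the 10 with the largest fall among those with a mean FPKM of at least 1 and with every library of one group above every library of the other, filled to 20 with the smallest p-values where fewer existed, and up to 2 members of each list with the smallest p. Uncharacterised genes were passed over. Genes named outside this rule are said to be chosen after their values were seen, and the 20 genes of the plot of fold changes were picked from the named genes after their values were seen.

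The shared control libraries were handled by 20 simulations of unchanged groups. Coordinates came from GENCODE release 29 on GRCh38, joined by NCBI gene identifier, which matched 12360 of the tested genes. A correction of each library for GC content and transcript length used values available for 99.1% of genes. Replicate numbers recur in all 3 groups, and a fit with the number as a block was one of the alternatives.

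Other alternatives were limma on log2(FPKM + 1) and on log2(FPKM + 0.1), no filter, FPKM of at least 5 in 3 libraries, quantile normalization, DESeq2 size factors in edgeR, library totals without TMM factors, removal of MTRNR2L2 and MTRNR2L8, only the groups compared, DESeq2, limma-voom and leaving out each library in turn.

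Scripts were tested on simulated counts for 12470 genes with real means and library sizes. In the simulated CAF against hOMF exosome comparison 79% of 100 genes changed 1.5-fold and 88% of 100 genes changed 2-fold were recovered, and 6.70% of calls were false. For CAF exosome against control the shares were 73%, 85% and 8.67%, and for hOMF exosome against control 71%, 91% and 7.43%. In the simulated CAF exosome against control comparison, 10 of 10 lists moved by the simulation and 0 of 30 unmoved lists were called. The simulated genes varied independently of each other and the lists were random. The result therefore does not show how often unmoved lists of correlated genes would be called.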

Results

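Poly(A) RNA was sequenced from Cal-27 cells, a human cell line of tongue squamous carcinoma. The cells had been co-cultured for 48 h with exosomes of cancer-associated fibroblasts (CAF exosomes) or with exosomes labelled hOMF, or had been kept as a control group. Exosomes are small membrane vesicles that cells release and that carry protein, lipid and RNA. Each of the 3 groups held 3 libraries, which the labels call replicate samples without stating separate cultures, so the p-values measure only the spread between these samples, which may be technical. Estimated counts summed to between 11192908 and 12779101 per library, and 12470 of the 16366 listed genes had enough counts to be tested. Levels are given as CPM, counts scaled by library size, with the SD over the 3 libraries of a group, and changes as log2 fold changes with their standard error (SE), from edgeR's quasi-likelihood test over all 9 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. In a principal component analysis of the libraries, the first component held 39.7% of the variance and placed the control libraries at 18.8, 21.3 and 29.8 and the 6 exosome libraries between -16.6 and -8.38. Control replicate 3 lay farthest out, at 29.8 on the first component and -17.9 on the second.

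Cal-27 cells given CAF exosomes were compared with control cells to ask how these exosomes change expression in the carcinoma cells. Genes of fatty acid synthesis and lipid handling were higher, as were genes of antigen presentation by MHC class II, while genes of DNA replication, mitosis, the immediate early response and inflammatory cytokines were lower. These directions come from camera with a preset correlation, and with an estimated correlation none of the lists was called (adjusted p between 0.0528 and 0.379). SREBF1, which encodes the transcription factor SREBP-1 that drives lipogenic genes, rose from 396 ± 23.9 to 750 ± 31.5 CPM (SD, n = 3), a log2 change of 0.92 (SE 0.07). FASN, the fatty acid synthase, rose by 0.82 (SE 0.08). IL6, an inflammatory cytokine, fell by 1.60 on the log2 scale (SE 0.18), from 9.54 ± 0.728 to 3.14 ± 0.755 CPM.

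Of the 12470 genes tested, 1186 were higher and 1078 lower with CAF exosomes than in control, 2264 or 18.2% together, and 4094 genes had an unadjusted p under 0.05. Most changes were small: 390 called genes rose and 168 fell by at least 1.5 times, and 97 rose and 45 fell by at least 2 times. Leaving out 1 library moved the count by over 1.5 times for CAF exosome replicate 3 (1343 genes), control replicate 2 (1389) and control replicate 3 (1442). The share of calls that were higher, 52.4%, was 63.1% when libraries were scaled by their totals without TMM factors, 63.3% with limma on log2(FPKM + 1) and 64.0% with a pseudocount of 0.1. After a correction for GC content and transcript length the balance turned the other way, with 44.0% of calls higher (1345 higher, 1711 lower).

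Of the 20 listed genes of fatty acid synthesis and lipid handling that were tested, 13 rose and 1 fell (14 and 1 adjusted over the list alone), with a median of 0.43. The list as a whole was higher than other genes by camera with a preset correlation (adjusted p = 1.18e-16), and the adjusted p = 0.0528 with an estimated correlation. Besides SREBF1 and FASN, the members that rose include 3 that handle cholesterol rather than make fatty acids, here named after their values were seen. ABCA1 and ABCG1, which export cholesterol from cells, rose by 2.18 (SE 0.24) and 2.26 (SE 0.36), and MYLIP, a ubiquitin ligase that degrades the LDL receptor, rose by 1.03 (SE 0.14). ABCA1 could be tested under only 18 of the 22 alternatives and kept its call in those. ABCG1 could be tested under 21, and its call was lost with quantile normalization. SCD, the stearoyl-CoA desaturase, was among the most abundant transcripts and rose from 7303 ± 778 to 11633 ± 1571 CPM. The member that fell was FADS2, a fatty acid desaturase, by 0.37 (SE 0.12, adjusted p = 0.0433), a call lost under 13 of 22 alternatives, which include leaving out CAF exosome replicate 2 or 3, hOMF exosome replicate 2 or 3, or control replicate 2 or 3. Of 24 genes of cholesterol synthesis, 10 rose and 0 fell (12 and 0 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation). INSIG1, an endoplasmic reticulum protein that holds back SREBP processing, rose by 0.65 (SE 0.08), and MSMO1, a sterol oxidase of the pathway, rose by 0.51 (SE 0.10).

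Of 12 genes of MHC class II presentation, 9 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 0.0839 with an estimated correlation). HLA-DRB1 rose by 0.47 (SE 0.07) and HLA-DRA by 0.46 (SE 0.07), the latter from 107 ± 4.92 to 146 ± 4.47 CPM, and CIITA, the transactivator of class II genes, rose by 0.70 (SE 0.12). Of 9 genes of drug metabolism and the aryl hydrocarbon receptor, 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.0839 with an estimated correlation). They were led by CYP1A1, a cytochrome P450 and target of that receptor, at 1.95 (SE 0.24), and CYP4F11 at 0.68 (SE 0.09).

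Squamous and Notch genes moved too. Of 18 basal keratinocyte genes, 6 rose and 0 fell (6 and 0 adjusted over the list alone, adjusted p = 0.399 with an estimated correlation). KRT5, a keratin of basal keratinocytes, rose from 748 ± 67.9 to 1232 ± 36.6 CPM and its partner KRT14 rose by 1.14 (SE 0.18). Of 17 keratinocyte differentiation genes, 1 rose and 4 fell (1 and 4 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation). S100A7 and S100A8, which encode calcium-binding proteins of inflamed epithelium, fell by 1.18 (SE 0.09) and 0.71 (SE 0.10). Of 12 Notch genes, 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation), among them the ligand DLL1 at 0.56 (SE 0.08) and the receptor NOTCH3 at 0.48 (SE 0.10).

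Genes of the cell cycle were lower. Of 37 genes of DNA replication and S phase, 23 fell and 0 rose (31 and 0 adjusted over the list alone), with a median of -0.39 and an adjusted p = 0.379 with an estimated correlation. RRM2, a subunit of ribonucleotide reductase, fell by 0.88 (SE 0.10), from 92.3 ± 12.3 to 50.1 ± 1.53 CPM, and CCNE2, cyclin E2, fell by 1.54 (SE 0.20). The 23 became 11 without control replicate 3, 12 without CAF exosome replicate 3 and 15 without CAF exosome replicate 1. The control libraries themselves differed in the mean level of this list, from 0.18 to 0.58 on the log2 scale relative to the mean of all libraries. Of 35 genes of G2 and mitosis, 18 fell and 0 rose (26 and 0 adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), including MKI67, the proliferation antigen Ki-67, by 0.62 (SE 0.09), and FOXM1, a mitotic transcription factor, by 0.54 (SE 0.08).

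Of 33 NF-kB targets and cytokines, 17 fell and 3 rose (18 and 3 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation). CSF2, which encodes the growth factor GM-CSF, fell from 60.1 ± 5.08 to 23.9 ± 3.53 CPM, and CXCL8, the neutrophil chemokine IL-8, fell by 0.46 (SE 0.07). The 3 that rose, named after their values were seen, were the acute phase genes SAA1 (0.49) and SAA2 (0.68) and the adaptor gene TRAF1 (0.52). Of 32 immediate early and MAPK feedback genes, 13 fell and 0 rose (15 and 0 adjusted over the list alone, adjusted p = 0.261 with an estimated correlation), among them the phosphatase genes DUSP1, by 0.90 (SE 0.11), and DUSP5, by 0.55 (SE 0.07). Of 20 heat shock genes, 9 fell and 0 rose (11 and 0 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation), including HSPA8, a constitutive chaperone, by 0.59 (SE 0.09). Of 28 ribosome biogenesis genes, 7 fell and 0 rose (12 and 0 adjusted over the list alone, adjusted p = 0.428 with an estimated correlation), including NOLC1, a nucleolar protein gene, by 0.44 (SE 0.10). Of 35 hypoxia and glycolysis genes, 10 fell and 2 rose (12 and 3 adjusted over the list alone, adjusted p = 0.547 with an estimated correlation), and LDHA, lactate dehydrogenase A, fell by 0.44 (SE 0.08). Of 34 genes of the integrated stress response and amino acid supply, 7 rose and 4 fell (12 and 4 adjusted over the list alone, adjusted p = 0.547 with an estimated correlation), with the cystine transporter gene SLC7A11 higher by 0.87 (SE 0.10) and the transcription factor gene ATF5 lower, at -0.54 (SE 0.10). None of the 76 ribosomal protein genes was called by edgeR and none adjusted over the list alone, although camera with a preset correlation gave an adjusted p = 0.00796 for a median of -0.10, and the adjusted p = 0.731 with an estimated correlation.

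Of 15 tested markers of fibroblasts, the source of the exosomes, 6 rose and 1 fell (6 and 1 adjusted over the list alone, adjusted p = 0.379 with an estimated correlation). The collagen gene COL6A1 rose by 0.64 (SE 0.11) and CCDC80 by 0.70 (SE 0.12), while COL1A1, an abundant fibroblast collagen named after its values were seen, stood at 43.3 ± 1.05 CPM against 37.2 ± 3.48 in control (adjusted p = 0.138). Among other fibroblast genes, named after their values were seen, the call of COL6A2 was lost under 13 of 21 alternatives and that of ACTA2 under 4 of 22. The markers summed to 1646 ± 106 CPM with CAF exosomes and 1429 ± 154 CPM in control. These sums rest largely on 1 gene, SPARC, the most abundant marker. It stood at 740, 694 and 703 CPM with CAF exosomes and at 595, 564 and 458 CPM in control. The sums therefore do not show a rise of fibroblast transcripts in general. The mean level of the markers on the log2 scale was -0.06 in CAF exosome replicate 2, apart from 0.14 and 0.17 in replicates 1 and 3. The marker that fell, S100A4, a calcium-binding protein gene named after its values were seen, was at -0.37 (SE 0.12), a call lost under 7 of 22 alternatives, among them leaving out any CAF exosome library or control replicate 1 or 3. Of 7 leukocyte markers, 1 fell and 0 rose (1 and 0 adjusted over the list alone). The fall was that of CORO1A, at 3.3, 4.6 and 17.1 CPM in control replicates 1 to 3 and 2.3, 3.9 and 2.3 CPM with CAF exosomes. Its call was lost under 8 of 21 alternatives, among them leaving out control replicate 3 or CAF exosome replicate 1 or 3.

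The 10 called genes with the largest rise held STRA6, a retinol transporter gene, from 0.879 ± 0.348 to 3.97 ± 0.197 CPM, CYP1A1, and PADI1, a peptidylarginine deiminase gene, from 3.07 ± 0.735 to 10.4 ± 1.49 CPM. C11orf71 (1.47) was among them, and KLRK1 (1.52), CRYBB3 (3.17), SAA2-SAA4 (1.78) and SLCO1B7 (1.42) were counted in part from reads shared with other genes and are uncertain. The 10 with the largest fall held the cytokine genes IL6, IL24 (-1.44), CSF2 and CSF3 (-1.25), and CCNE2, FOXQ1 (-1.20) and PIP (-1.66), while ANKRD36C (-1.22) and SMIM11B (-1.67) rest in part on shared reads. The rule for named genes required every library of one group to lie above every library of the other, so that separation is not further support. Calls were lost for PGAM2 (1.85) without CAF exosome replicate 2 or 3 or control replicate 2 or 3, for APOD (1.58) without CAF exosome replicate 2 or 3 or control replicate 2, for SLCO1B7 without CAF exosome replicate 1 or control replicate 3, for BCL2A1 (-1.37) without CAF exosome replicate 3 or control replicate 2, and for SMIM11B without any CAF exosome library or control replicate 3. The call of SMIM11B was also lost with DESeq2, limma-voom, limma on log2(FPKM + 1), a pseudocount of 0.1 and quantile normalization. Quantile normalization also ended the calls of CRYBB3 and SLCO1B7.

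In GRCh38 with GENCODE release 29, SREBF1 lies on chromosome 17 from 17810399 to 17837002 on the minus strand and FASN on chromosome 17 from 82078333 to 82098332 on the minus strand. CYP1A1 spans 74719542 to 74725610 and STRA6 74179466 to 74212267 on the minus strand of chromosome 15. CSF2 lies on chromosome 5 from 132073790 to 132076170 and IL6 on chromosome 7 from 22725884 to 22732002, both on the plus strand. All are protein-coding, and each count covers the exons of the gene. Exons of RAI1 overlap SREBF1, those of CCDC33 overlap STRA6, those of STEAP1B overlap IL6 and those of INTS8 overlap CCNE2, each on the opposite strand. Exons of DBNL overlap PGAM2 and those of RBM7 overlap C11orf71 in the same way. With CAF exosomes PGAM2 stood at only 1.34, 1.70 and 1.75 CPM and C11orf71 at 1.87, 2.13 and 3.00 CPM. The strand setting of the counting is not given in the sources used here, so reads of such pairs cannot be told apart.

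**Figure D1:**
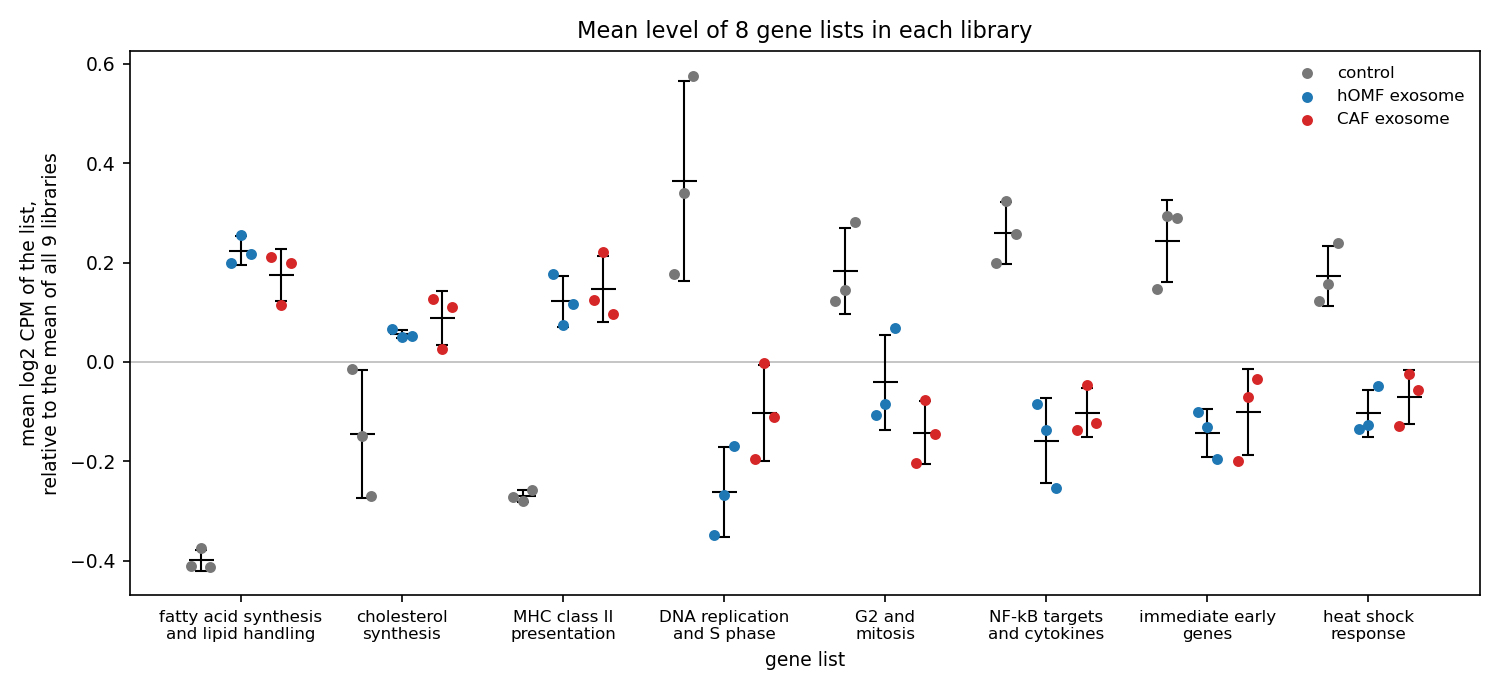
Mean log2 CPM of the members of 8 gene lists (y axis, relative to the mean of all 9 libraries) in each library, with the horizontal bar and whiskers giving the mean and SD of the 3 libraries of a group. For fatty acid synthesis and lipid handling, control lay at -0.40 ± 0.02, hOMF exosome at 0.22 ± 0.03 and CAF exosome at 0.18 ± 0.05, while for DNA replication control lay at 0.36 ± 0.20, hOMF exosome at -0.26 ± 0.09 and CAF exosome at -0.10 ± 0.10.

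Cells given hOMF exosomes were compared with the same control cells, which gives the response to exosomes that do not come from CAF. The response had the same outline: fatty acid and lipid handling genes and MHC class II genes were higher, and genes of DNA replication, cytokines and the immediate early response were lower. With an estimated correlation none of these lists was called (adjusted p between 0.0528 and 0.333). SREBF1 rose to 808 ± 30.7 CPM (SD, n = 3), a log2 change of 1.03 (SE 0.07), and FASN by 0.99 (SE 0.08). CSF2 fell by 1.55 (SE 0.10), from 60.1 ± 5.08 to 20.6 ± 1.55 CPM, and S100A7 by 1.42 (SE 0.09), from 66.6 ± 7.54 to 24.9 ± 1.43 CPM.

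With hOMF exosomes 1475 genes were higher and 1421 lower than in control, 2896 or 23.2% of those tested, and 4575 had an unadjusted p under 0.05. At least 1.5-fold changes were called for 510 higher and 271 lower genes, and at least 2-fold changes for 160 higher and 60 lower. The count became 1695 without hOMF exosome replicate 2. The higher share of calls, 50.9%, was 67.0% without TMM factors, 68.1% with limma on log2(FPKM + 1) and 68.3% with a pseudocount of 0.1. After the correction for GC content and transcript length it was 42.8% (1575 higher, 2104 lower).

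Of the 37 genes of DNA replication and S phase, 30 fell and 0 rose (33 and 0 adjusted over the list alone), with a median of -0.56 and an adjusted p = 0.333 with an estimated correlation. RRM2 fell by 0.98 (SE 0.10) and CDC6, which loads the replicative helicase, by 0.90 (SE 0.10). Without control replicate 3 the median was -0.42 and 23 members fell. Of the 35 genes of G2 and mitosis, 12 fell and 0 rose (12 and 0 adjusted over the list alone, adjusted p = 0.539 with an estimated correlation), with MKI67 lower at -0.54 (SE 0.09) and FOXM1 at -0.47 (SE 0.08). Of 28 ribosome biogenesis genes, 16 fell and 0 rose (20 and 0 adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), including NOP16, by 0.68 (SE 0.12), and NOLC1, by 0.58 (SE 0.10).

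Of the 20 genes of fatty acid synthesis and lipid handling, 15 rose and 1 fell (16 and 1 adjusted over the list alone, adjusted p = 0.0528 with an estimated correlation), again with ABCA1 (2.46, SE 0.23), ABCG1 (2.61, SE 0.35) and MYLIP (1.21, SE 0.14) among the risers and FADS2 (-0.56, SE 0.12) as the member that fell. Of 24 genes of cholesterol synthesis, 9 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.547 with an estimated correlation). INSIG1 rose by 0.67 (SE 0.08), and the member that fell was NSDHL, a sterol dehydrogenase named after its values were seen, at -0.26 (SE 0.07). Of 12 genes of MHC class II presentation, 6 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 0.184 with an estimated correlation), including HLA-DRB1 at 0.41 (SE 0.07) and HLA-DQB1 at 0.50 (SE 0.09). Of 9 genes of drug metabolism and the aryl hydrocarbon receptor, 6 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 0.0839 with an estimated correlation), with CYP1A1 at 2.25 (SE 0.23).

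Of 33 NF-kB targets and cytokines, 18 fell and 3 rose (22 and 3 adjusted over the list alone, adjusted p = 0.272 with an estimated correlation), including CXCL1, a neutrophil chemokine, by 0.95 (SE 0.09), from 771 ± 78.7 to 398 ± 43.6 CPM. The 3 that rose were SAA1 (0.33), SAA2 (0.55) and TRAF1 (0.49), named after their values were seen. Of 32 immediate early genes, 16 fell and 0 rose (19 and 0 adjusted over the list alone, adjusted p = 0.261 with an estimated correlation), including the transcription factor gene KLF6, by 0.80 (SE 0.08). Of 20 heat shock genes, 11 fell and 0 rose (11 and 0 adjusted over the list alone, adjusted p = 0.307 with an estimated correlation), including HSPA8, by 0.84 (SE 0.09). Of 35 hypoxia and glycolysis genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone, adjusted p = 0.390 with an estimated correlation), including NDRG1, a hypoxia-induced gene, by 0.77 (SE 0.10). Of 16 senescence genes, 4 fell and 0 rose (4 and 0 adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), among them IL6, by 1.51 (SE 0.18), and CXCL8, by 0.70 (SE 0.07), which are secreted factors that the cytokine list also holds. Of 31 genes of exosome formation, 10 fell and 2 rose (11 and 2 adjusted over the list alone, adjusted p = 0.383 with an estimated correlation), with SDC4, a syndecan, at -0.79 (SE 0.08). Of 17 keratinocyte differentiation genes, 5 fell and 2 rose (7 and 3 adjusted over the list alone, adjusted p = 0.399 with an estimated correlation), led by S100A7 and by S100A9, a partner of S100A8, at -0.79 (SE 0.09).

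Of the 15 fibroblast markers, 6 rose and 1 fell with hOMF exosomes (6 and 1 adjusted over the list alone, adjusted p = 0.379 with an estimated correlation), with CCDC80 at 0.88 (SE 0.12) and COL6A1 at 0.59 (SE 0.11), and they summed to 1588 ± 40.4 CPM. SPARC again held a large part of the sum, at 680, 626 and 643 CPM with hOMF exosomes. S100A4 fell by 0.48 (SE 0.12), a call lost without hOMF exosome replicate 2. The call of COL6A2, named after its values were seen, was lost under 3 of 21 alternatives. COL1A1, at 43.3 ± 6.23 CPM, was not called (adjusted p = 0.124). Of 7 leukocyte markers, 4 fell and 0 rose (4 and 0 adjusted over the list alone), and camera gave an adjusted p = 0.169.

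The 10 called genes with the largest rise held CYP1A1, PADI1 (2.00), STRA6 (1.88), PLAC8 (1.74), PGAM2 (2.30) and SERPINF1, which encodes the secreted factor PEDF and rose from 5.62 ± 1.55 to 16.4 ± 2.30 CPM. KLRK1 (1.83), CRYBB3 (2.71), CGB2 (2.40) and OR2A1 (1.64) were counted in part from reads shared with related genes. CGB2 also rests on few reads, at 0, 0.09 and 0.479 CPM in the control libraries. The call of CRYBB3 was lost with limma on log2(FPKM + 1), with a pseudocount of 0.1 and with quantile normalization. The 10 with the largest fall held CSF2, IL6, IL24 (-1.51), IL17C (-1.57), S100A7, CCNE2 (-1.85), BCL2A1 (-1.55), IGFL1 (-2.50), and MMP7, the matrix metalloproteinase matrilysin, at -1.43 (SE 0.22). The change of IGFL1 rests on few reads, with 0.52, 0.087 and 0.076 CPM in the hOMF exosome libraries and 2.182, 0.903 and 0.877 CPM in control. LAIR1 (-1.88), counted in part from shared reads, rested on 1 control library, with 19.5 CPM in control replicate 3 and 3.00 and 2.89 CPM in the others, and its call was lost without control replicate 3 or any of the hOMF exosome libraries. It was also lost with DESeq2 and limma-voom.

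**Figure D2:**
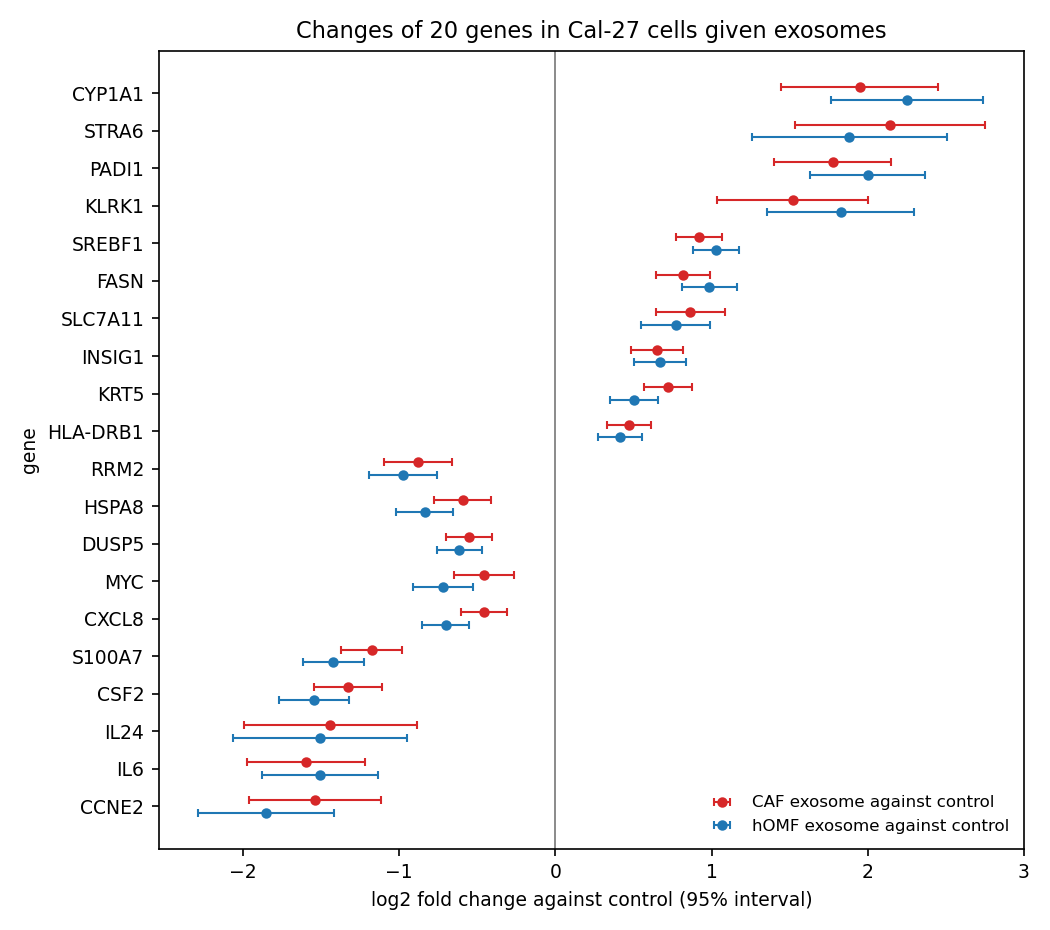
Log2 fold changes against control (x axis) of 20 genes (y axis) with CAF exosomes and with hOMF exosomes, as points with 95% intervals from edgeR. Both exosome kinds moved each gene in the same direction, from CYP1A1 at 1.95 and 2.25 to CCNE2 at -1.54 and -1.85. The 20 genes were picked after their values were seen and both comparisons share the control libraries. Their common direction is therefore not separate support for a shared response.

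Both exosome responses were set side by side across genes. Of the called genes, 911 were higher and 842 lower in both comparisons, 1753 together, against 140 and 123 for independent lists of the same sizes, and 0 genes were called in opposite directions. A further 511 genes were called with CAF exosomes alone and 1143 with hOMF exosomes alone, which does not show a difference between the kinds: 0 of the former and 1 of the latter, GJB2, were also called in the direct comparison of both kinds. The log2 fold changes correlated across genes with r = 0.86, where genes are not independent replicates. In 20 simulations of unchanged groups sharing the control libraries, r averaged 0.49 (0.45 to 0.54) and at most 1 gene was called in both. Over all genes 83.7% had the same sign in both comparisons, against 66.8% in the simulations. The covariance was 0.110 against a simulated 0.0163, an excess of 0.0940. With 3 control libraries the controls could not be divided into separate sets of at least a pair each, so part of the excess of shared calls over independent lists may come from the shared controls. A covariance of log2 CPM changes that never used the same control library on both sides was 0.0725, with r = 0.98 after removal of noise. Noise of single control libraries is therefore argued against as the source of the correlation, while a shift common to all controls would remain. Leaving out 1 library moved the 1753 shared calls by over 1.5 times for CAF exosome replicate 3 (1095), hOMF exosome replicate 2 (1159), control replicate 2 (1090) and control replicate 3 (1099).

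The direct comparison of CAF exosomes with hOMF exosomes, which the series design names, asked what sets the exosomes of cancer-associated fibroblasts apart, and the cells of both groups were close to each other. GJB2, which encodes the gap junction protein connexin 26, was higher with CAF exosomes, at 224 ± 19.4 CPM against 156 ± 5.20 CPM with hOMF exosomes (SD, n = 3), a log2 difference of 0.52 (SE 0.08). ZNF114, a zinc finger protein gene, was lower with CAF exosomes, at 38.1 ± 2.68 against 54.1 ± 2.61 CPM, a log2 difference of -0.51 (SE 0.08). In control, GJB2 stood at 239, 211 and 209 CPM in the 3 libraries and ZNF114 at 65.3, 62.8 and 66.4 CPM. Against control, GJB2 fell by 0.49 (SE 0.08) with hOMF exosomes and was at 0.03 (SE 0.08) with CAF exosomes, while ZNF114 fell by 0.77 (SE 0.08) with CAF exosomes and by 0.26 (SE 0.08) with hOMF exosomes.

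These were the 2 genes that edgeR called among 12470, both with an adjusted p = 0.0439, and 947 genes (7.59%) had an unadjusted p under 0.05. DESeq2 called 36 and limma-voom 0, and edgeR fitted to the 6 exosome libraries alone called 0. At an adjusted p under 0.1 edgeR gave 10 genes, 6 higher and 4 lower with CAF exosomes. The precision was enough to bound most genes: the 95% interval of the log2 difference had a median half-width of 0.21 and excluded a 1.5-fold change for 84.1% of genes and a 2-fold change for 95.4%. The call of GJB2 was lost under 14 of 22 alternatives and that of ZNF114 under 16 of 22, among them leaving out any one of the exosome libraries or control replicate 2, and for ZNF114 also control replicate 1 and taking the replicate number as a block. Without control replicate 3, 8 genes were called.

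GJB2 lies on the minus strand of chromosome 13 from 20187463 to 20193010, and ZNF114 on the plus strand of chromosome 19 from 48270102 to 48287608 (GRCh38, GENCODE release 29), and both are protein-coding. Exons of ZNF114-AS1 overlap ZNF114 on the opposite strand, and part of the ZNF114 count came from shared reads.

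The genes next in order were not called and are given as values. CCL20, a chemokine that attracts lymphocytes and dendritic cells, differed by 0.53 (SE 0.09, adjusted p = 0.0593), LFNG, a glycosyltransferase that modifies Notch receptors, by 0.50 (SE 0.08, adjusted p = 0.0674), and PFKFB4, a regulator of glycolysis, by 0.59 (SE 0.11, adjusted p = 0.0948), though its count rests on reads shared with other genes. ARRB1 (-0.50), KCNK3 (-0.58), TSC22D3 (-0.45), SDC4 (0.43) and EFNB1 (0.40) had the same adjusted p = 0.0948 as PFKFB4. CSRP1, PTHLH, TAF9B, MAT2A, SLC43A3, GALNT1, TLCD3A, FST, CD81 and ZBED6CL had adjusted p between 0.104 and 0.195.

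Gene lists differed by little. Camera with a preset correlation called 15 of 42 lists, 14 of them higher with CAF exosomes, fry called 2, and with an estimated correlation 0 lists were called. No member of these 15 lists was called by edgeR over all genes. DNA replication and S phase had a median of 0.16 over 37 genes, with 0 called adjusted over the list alone and an adjusted p = 0.547 with an estimated correlation, and its leading member MCM5, a helicase subunit gene, differed by 0.30 (SE 0.09, adjusted p = 0.395). Complement and coagulation had a median of 0.13 over 20 genes, with 3 higher adjusted over the list alone and an adjusted p = 0.329 with an estimated correlation, led by CFB, complement factor B, at 0.31 (SE 0.07, adjusted p = 0.197). The unfolded protein response had a median of 0.13 over 21 genes, with 0 called adjusted over the list alone and an adjusted p = 0.307 with an estimated correlation. Mitosis genes were the 1 list lower with CAF exosomes, with a median of -0.07 over 35 genes, 3 lower adjusted over the list alone and an adjusted p = 0.554 with an estimated correlation. NF-kB targets and cytokines were called higher by camera (adjusted p = 0.00321), with a median of 0.06 over 33 genes, 1 higher adjusted over the list alone and an adjusted p = 0.455 with an estimated correlation. Among other immune lists, which were not called, MHC class II (0.07), type I interferon (0.01), interferon gamma (-0.07), MHC class I (0.04) and checkpoint ligands (0.02) had medians near 0.

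**Figure D3:**
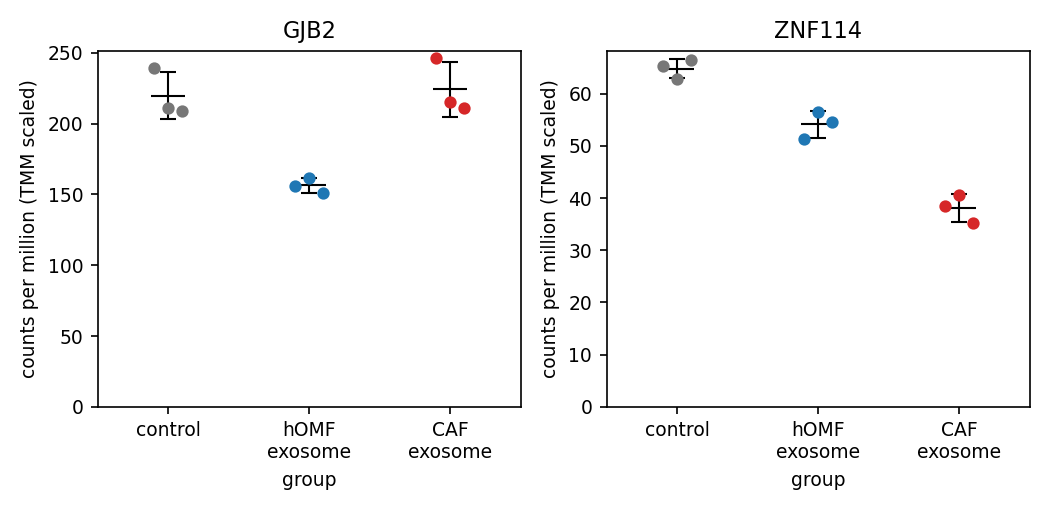
CPM (y axis, TMM scaled, from 0) of GJB2 and ZNF114 in each library of the 3 groups, with the bar and whiskers giving the mean and SD of 3 libraries. GJB2 averaged 224 CPM with CAF exosomes and 156 CPM with hOMF exosomes, and ZNF114 averaged 38.1 and 54.1 CPM.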

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

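In this part the tests of carried-over RNA were chosen after the result was seen, and the predictions of the others were written once the patterns were known but before the values of the tests were.

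Of the genes tested, GJB2 and ZNF114 differed between the responses to the 2 exosome kinds by a test of the difference itself, with log2 differences of 0.52 and -0.51 (CAF minus hOMF exosome, adjusted p = 0.0439 for each by edgeR). The call of ZNF114 rests in part on shared reads.

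In the comparison of CAF with hOMF exosomes, edgeR on the 6 exosome libraries alone called 0 genes for the real division into 3 and 3. All 10 divisions necessarily reach 0, so their number says nothing about that result. The highest number of another division was 66, which came from CAF exosome replicates 1 and 3 with hOMF exosome replicate 3 against the remaining libraries and points to a structure of the samples that does not follow the exosome kind. Those 3 libraries lay at 9.70, 1.01 and 4.58 on the second principal component. CAF exosome replicate 2 and hOMF exosome replicates 1 and 2 lay at -10.7, -7.92 and -1.70. The first 3 also had the larger shares of MTRNR2L2 and MTRNR2L8 counts (4.76%, 3.97% and 3.95% against 3.53%, 3.52% and 3.69%). The cause of this structure was not tested. In the fit to all 9 libraries 947 genes had an unadjusted p under 0.05, DESeq2 called 36 and limma-voom 0.

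With CAF exosomes 2264 genes and with hOMF exosomes 2896 genes differed from control. A trend with GC content or transcript length is argued against, since 98.1% of the called genes with CAF exosomes and 97.4% with hOMF exosomes were still called in the same direction after each library was corrected for it. RNA carried in with the exosomes would lower all other genes by a common factor, which scaling removes if that RNA covers few genes. Of the called genes, 7.42% and 9.36% fell by more than 1.5 times. These falls were known when the test was chosen, and carried RNA of many genes could leave the others lower after scaling. The test therefore cannot decide, and carried RNA stays open for genes that fell and for those that rose. A difference in handling or medium between treated and control wells is confounded with the treatment and was not tested. Among 10 divisions of the 6 libraries, 1 gave as many genes as the real one for CAF exosomes (2087 genes, highest other 0) and 1 for hOMF exosomes (2878 genes, highest other 0), which is too few divisions for a share under 0.05.

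Genes of DNA replication were lower in both exosome groups, and control replicate 3 had the highest level of them. That library alone is argued against as the source, since without it the higher of both medians was -0.32, and so is GC content or length, since after the correction the higher median was -0.40. The count of members called lower with CAF exosomes did fall from 23 to 11 without control replicate 3. A response of the cells to exosomes may account for the lower level, and a difference in growth or density between treated and control cultures, which the design confounds with treatment, stays open as well. Neither was tested.

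The response to CAF exosomes ran along the same axis as that to hOMF exosomes but may be smaller, with a slope of 0.85 of the CAF on the hOMF response after removal of shared noise. One exosome library alone is argued against, since leaving out each of the 6 gave slopes of at most 0.91. Among 10 divisions of the exosome libraries, 3 gave as large a difference of variances (a log2 ratio of 0.418 for the real division, 0.472 for the highest other), and 10 divisions cannot give a share under 0.05. The dose of the exosomes is not given in the sources used here, so a dose difference and a difference of kind cannot be told apart, and neither was tested.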

How the results depend on the processing

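Limma on log2(FPKM + 1), the test first written for a table without counts, was kept as an alternative once counts were found. Scaling without TMM factors, the GC and length correction, removal of MTRNR2L2 and MTRNR2L8, leaving out libraries for the correlation of both responses, and leaving out libraries or blocking for the shared calls were chosen after seeing the data, and the other alternatives were planned. For CAF against hOMF exosomes the 2 genes of edgeR became 0 with limma on log2(FPKM + 1), with a pseudocount of 0.1, with quantile normalization, without TMM factors, without MTRNR2L2 and MTRNR2L8, with only the groups compared and with limma-voom, 4 with FPKM of at least 5, 11 after the GC and length correction (7 higher, 4 lower) and 36 with DESeq2 (28 higher, 8 lower), beside 947 genes at an unadjusted p under 0.05, and leaving out 1 library gave 0 to 8. Against control, 1825 to 3056 genes were called with CAF exosomes and 2264 to 3679 with hOMF exosomes, and 1343 to 2389 and 1695 to 3096 with 1 library left out. Fixed lists called with an estimated correlation were 0 in each comparison, and fry called 2, 17 and 20 for CAF against hOMF exosomes, CAF exosomes against control and hOMF exosomes against control. The correlation of both responses was 0.897 with FPKM of at least 5 and 0.80 to 0.873 with 1 library left out, and 1090 to 1720 genes were shared. The cause of these moves was not tested. Replicate numbers did not pair the samples, since deviations of same-numbered libraries correlated at -0.15 to 0.14. The replicate block gave 2 (of the 2 of edgeR it kept GJB2 and lost ZNF114), 2101 and 2718 genes, 15, 17 and 15 lists, a correlation of 0.858 and 1632 shared genes. CD274 changed sign between alternatives and was called in none. With CAF exosomes it was at 0.0133 without control replicate 2. With hOMF exosomes it was at -0.24 with limma on FPKM, -0.40 with a pseudocount of 0.1, -0.35 with quantile normalization, -0.00436 with the replicate block, -0.0384 after the GC and length correction, -0.0348 with limma-voom, -0.28 without hOMF exosome replicate 2, -0.0255 without control replicate 1 and -0.0528 without control replicate 3, and leaving out 1 library gave -0.28 to 0.19. Of the remaining values of named genes, 6584 kept direction and side of the threshold, 236 lost their call and 66 gained one. Of the values of lists that camera with a preset correlation had called, 690 kept both and 109 lost their call. Lists it had not called were left out of these numbers, so a gain could not appear. Some alternatives did call such lists: of the 20 lists that fry called for hOMF exosomes against control, 14 were shared with camera.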

Other observations

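In this part the test of cholesterol load was chosen after the result was seen, and the test of liver X receptor targets was written before the values of those targets were seen. The reading of the latter was changed after its result was seen: an interval was added, because the first rule, under which 14.3% of targets argued against these receptors, was too firm for so few targets.

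Of 37 type I interferon genes, 6 rose and 1 fell with CAF exosomes (6 and 1 adjusted over the list alone) and 9 rose and 2 fell with hOMF exosomes (9 and 3 adjusted over the list alone), and camera called the list in neither (adjusted p = 0.246 and 0.364). OASL, an interferon-induced gene of the oligoadenylate synthetase family, rose by 1.23 (SE 0.17) with CAF exosomes and 1.15 (SE 0.17) with hOMF exosomes, while its relative OAS3 fell by 0.45 (SE 0.08) and 0.69 (SE 0.08). Of 21 genes of MHC class I presentation, 5 rose and 1 fell with CAF exosomes (7 and 1 adjusted over the list alone, camera adjusted p = 0.0533) and 6 rose and 1 fell with hOMF exosomes (6 and 1 adjusted over the list alone, adjusted p = 0.241). Of 20 checkpoint ligands, 2 rose and 1 fell with CAF exosomes and 3 rose and 4 fell with hOMF exosomes, the same numbers adjusted over the list alone. Of 23 interferon gamma genes, 3 rose and 0 fell with CAF exosomes (3 and 0 adjusted over the list alone, camera adjusted p = 0.479) and 7 rose and 1 fell with hOMF exosomes (7 and 2 adjusted over the list alone, adjusted p = 0.246). TNFSF9, the ligand of the T cell receptor 4-1BB, rose by 0.40 (SE 0.07) with either kind. CD274, which encodes PD-L1 and was chosen after its values were seen, was not called, at -0.09 (SE 0.23) with CAF and 0.01 (SE 0.23) with hOMF exosomes.

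Single genes of tissue remodelling and growth signals moved in both comparisons, without a call for their lists. MMP7, matrilysin, was at -0.89 (SE 0.21) with CAF exosomes and -1.43 (SE 0.22) with hOMF exosomes. Of 23 matrix proteases, 4 fell and 3 rose with CAF exosomes (5 and 3 adjusted over the list alone, camera adjusted p = 0.977) and 6 fell and 2 rose with hOMF exosomes (6 and 4 adjusted over the list alone, adjusted p = 0.190). Of 10 Wnt targets, 3 fell and 0 rose in each comparison, the same numbers adjusted over the list alone (camera adjusted p = 0.0762 and 0.0861), with the oncogene MYC at -0.46 (SE 0.09) and -0.72 (SE 0.09) and the Wnt antagonist gene DKK1 at -0.62 (SE 0.08) and -0.73 (SE 0.08).

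ABCA1, ABCG1, MYLIP and SREBF1 are targets of the liver X receptors, which sense oxidised sterols, and all 4 rose with both exosome kinds, so activation of these receptors was a candidate explanation. Of 13 further targets, 9 were in the table and 7 were tested, and 1 of the 7 was called higher in both comparisons, 14.3% (95% exact binomial interval 0.361% to 57.9%). That was MLXIPL, a lipogenic transcription factor gene, at 1.0 (SE 0.17) and 1.15 (SE 0.16), while PLTP, a phospholipid transfer protein gene, was at 0.90 (SE 0.29, adjusted p = 0.0415) and 0.80 (SE 0.29, adjusted p = 0.0601). With 7 targets the share cannot be told apart from the larger share set beforehand for activation, so the explanation stays open. Cholesterol brought in with the exosomes would lower the genes of cholesterol synthesis, and no such fall was seen, with 0.16 as the lower of both medians. The list was not called with an estimated correlation (adjusted p = 0.428 with CAF and 0.547 with hOMF exosomes), and the control libraries spread from -0.27 to -0.01 in its mean level, so the values speak against a fall and do not establish a rise.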
